A study of Mus musculus with 2 samples.

How the data were processed

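Lung cells of irradiated chimeric mice were profiled with 1 droplet-based 3′ single-cell RNA library, accompanied by 1 hashtag library from the same cells. Per the labels, the donor bone marrow was either Tgfbr2 fl/fl, called the control pool, or LyzM-Cre Tgfbr2 fl/fl, called the Tgfbr2-KO pool. Cells of 5 mice were pooled per genotype, and each genotype pool carried its own hashtag, B0301 for the control pool and B0303 for the Tgfbr2-KO pool. Mice of a pool carry no tag of their own, so there is 1 pool per genotype and no replicate. No significance test was therefore made and no p-value computed, and each value describes these 2 pools.

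The submitters' processing notes name Cell Ranger 8.0, Seurat 5.1.0 and the mouse genome build GRCm38. The matrix header gives Cell Ranger 8.0.0, and the step done with Seurat is not given in the sources used here, nor is the annotation version. The deposited matrix holds the count of unique molecular identifiers (UMIs) per gene and barcode, as whole numbers without normalization, for 22597 genes, 3 hashtags and 1172636 barcodes, so it was not filtered to cells. Per the file headers, the hashtag table gives for each of 4887 called cells the fraction of posterior probability for each of 4 states, which sum to 1. The deposited hashtag columns ending in cnts are log10 values: they equalled the log10 of the matrix hashtag count plus 1, with a maximum difference of 8.9e-16. The other deposited columns hold barcodes, gene IDs, gene symbols and the assignment of each cell by name.

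Cells assigned to B0301 or B0303 were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Of 4671 cells assigned to 1 hashtag, 101 were removed, which left 4570. Cells called multiplet, blank or unassigned entered no comparison. Doublets were handled by leaving out the 96 hashtag multiplets. Doublets within a hashtag cannot be seen this way, and the number expected from the multiplets and the pool sizes was 102, or 2.18% of the assigned cells. The doublet caller Scrublet, as included in scanpy 1.11.5, marked 1 of the 4570 cells, and its calls were not used.

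Counts were scaled to 10000 per cell and transformed as the natural log of the value plus 1. Clustering used 2000 variable genes without mitochondrial, ribosomal and sex-linked genes, 30 principal components, a shared nearest-neighbour graph of 15 neighbours and the Leiden algorithm at a resolution of 0.8, with both pools together and without integration. Markers of 17 lists were counted in each cluster, and names were given for CD206+, CD206-, monocyte-like, proliferating and structural cells only, so clusters with markers of other kinds, such as dendritic cells, keep their number. A marker counted as detected in a cluster at a log2 ratio above 0.5 over all other cells and at least 10 UMIs per 1000000 UMIs. A name needed at least 3 detected markers, and for monocyte-like, proliferating and structural cells also a marker among the 10 leading genes. Clusters with more detected markers of CD206+ than of CD206- interstitial macrophages joined the CD206+ class, and those with more of the CD206- kind joined the CD206- class. CD206 is the mannose receptor encoded by Mrc1, and the CD206- list holds MHC class II genes. The names rest on counts of markers that stand above other cells, so cells of the CD206- class need not lack Mrc1. Monocyte-like and structural cells also had to have low complement C1q, and clusters with very low UMIs were not put in a class. These last conditions and the order of the names were set after the clusters had been seen, so the names in the alternative clusterings depend on them. Clusters that met none of these conditions keep their number too.

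Values are UMIs summed over the cells of a pool and class, per 1000000 gene UMIs of that pool and class (UPM). Intervals are exact 95% intervals, Poisson for a UPM, conditional binomial for a ratio and Clopper-Pearson for a share. They cover counting error only, treat UMIs and cells as independent, and leave out differences between mice and between sorts. A count of 0 was set to a floor of 3 counts, which is 0.184 UPM in the control pool and 0.0976 UPM in the Tgfbr2-KO pool over all cells. Genes were compared in classes or clusters with at least 100 cells in both pools. Values within a class or cluster are also given for single clusters and parts with fewer cells. These go down to 86 Tgfbr2-KO cells in cluster 7, 41 in the larger part of cluster 5 and 28 control cells in cluster 0. The figure of the loci shows every cluster. A gene was counted with at least 100 UMIs summed over both pools and at least 100 UPM in 1 of them, and called different at 1.5-fold. Genes named for a whole group are given in its single clusters and parts without this minimum and mostly without intervals, so some rest on few UMIs. Named genes are, in all cells and in the 3 groups with the most cells, the 12 counted genes with the highest and the 12 with the lowest ratio, without mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, sex-linked and predicted genes. To these come Tgfbr2, Lyz2 and members of the lists of genes that met the same minimum, with up to 4 examples per list. A few genes that met this rule are not reported here. Lyz1 ranked among the named genes in a pair of classes and is given throughout beside Lyz2. The 27 lists were TGF-beta targets, TGF-beta pathway components, homeostatic tissue macrophage genes, interstitial macrophage core, CD206+ interstitial macrophage, MHC class II presentation, classical monocyte, patrolling monocyte, cell cycle, type I interferon response, inflammatory cytokines and NF-kB, chemokines, chemokine and growth factor receptors, myeloid transcription factors, lipid and phagolysosome, extracellular matrix and remodelling, integrins and adhesion, glycolysis and hypoxia, alternative activation, dissociation stress, mitochondrially encoded genes, alveolar macrophage, dendritic cell, neutrophil, T or NK cell, B or plasma cell, and structural lung cells. For each, the median log2 ratio of the members with at least 20 UMIs was set against 10000 random lists of the same size matched on level, as a description. Mx1, a member of the interferon list, is not among the genes of the matrix.

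The hashtag rule, the cell filter, the clustering settings, the marker and gene lists, the thresholds and the rule for named genes were fixed before the data were examined. Shares were also computed after clustering without the 716 genes that differed between the pools within a class. Other alternatives were a stricter and no cell filter, an assignment probability of at least 0.99, resolutions of 0.4 and 1.2, 1000 variable genes, thinning to 3000 UMIs, trimmed-mean scaling, totals without mitochondrial and ribosomal genes, means over cells, other minima and folds, leaving out or splitting clusters, and the subtraction of free RNA measured in droplets of at most 100 UMIs. Gene IDs were matched to the provided name table for 22503 of the 22597 genes, and coordinates come from a RefSeq table of GRCm38.p6. The comparison was tested on simulated data over 22597 genes, 50 of them at each of 4 folds. Of genes simulated at 1.75-fold 98% were called, of those at 1.25-fold 0%, and of 1336 unchanged genes 0. Both pools were drawn as Poisson counts around the control totals over all cells, without differences between cells or mice. The result therefore checks the calculation at that depth. It gives no rate of false calls for these 2 pools or for the smaller classes. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.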

Results

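Donor-derived lung monocytes and macrophages were compared between mice given Tgfbr2 fl/fl bone marrow without or with LyzM-Cre, which is meant to delete the TGF-beta receptor 2 gene in myeloid cells. The hosts were IM-DTR mice, in which diphtheria toxin depletes interstitial macrophages, and 50 ng of toxin was given 10 days before sacrifice, which frees the niche for donor cells. The sort took donor cells (CD45.1-CD45.2+) that were CD11b+ and CD64+ with low side scatter, and left out Ly6G+ neutrophils and SiglecF+ alveolar macrophages and eosinophils. Of 4887 called cells, 1933 carried the control hashtag, which is 39.6% (38.2 to 40.9), and 2738 carried the Tgfbr2-KO hashtag, which is 56.0% (54.6 to 57.4). A further 96 were multiplets (1.96%), 66 were unassigned (1.35%) and 54 were blank (1.10%). The median count of a cell's own hashtag was 535 UMIs in control cells, against 34 for that hashtag in Tgfbr2-KO cells. It was 961 UMIs in Tgfbr2-KO cells, against 60 for that hashtag in control cells. After filtering, the control pool held 1896 cells with 16298452 UMIs, and the Tgfbr2-KO pool 2674 cells with 30729204 UMIs. The median cell had 7785 UMIs and 2227 genes in the control pool and 10277.5 UMIs and 2727 genes in the Tgfbr2-KO pool. There was 1 pool of 5 mice per genotype and so no replicate.

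The targeted gene was examined first, to see what the 3′ counts show at the modified loci. Tgfbr2 (ENSMUSG00000032440, chromosome 9, 116087695 to 116175363 of GRCm38.p6) stood at 215 UMIs per 1000000 (UPM; 208 to 222) in the control pool and 195 UPM (190 to 200) in the Tgfbr2-KO pool, a log2 ratio of -0.14 that was 0.09 without cluster 0. In CD206- cells it stood at 207 UPM in the control pool and 240 UPM in the Tgfbr2-KO pool, in CD206+ cells at 295 and 315 UPM, with a log2 ratio of -0.21 in cluster 1 alone, and in cluster 5 at 155 and 129 UPM. The floxed exon is not given in the sources used here and 3′ tags can lie outside it, so these counts do not measure the deletion. Lyz2, which encodes the macrophage lysozyme, is the gene into which the LyzM-Cre allele is knocked. Lyz2 (ENSMUSG00000069516, chromosome 10, 117277541 to 117282272) stood at 13282 UPM in the control pool and 5949 UPM in the Tgfbr2-KO pool, 2.23-fold lower (2.22 to 2.25). The neighbouring lysozyme gene Lyz1 (ENSMUSG00000069515, chromosome 10, 117287795 to 117292868) went the other way, at 128 UPM and 917 UPM, 7.18-fold higher (6.87 to 7.52). In CD206- cells Lyz2 was 2.62-fold lower (2.58 to 2.66) and Lyz1 6.15-fold higher (5.70 to 6.65), a log2 ratio of 2.62 that was 3.67 without the cell filter, 3.37 with the stricter filter and 3.53 in classes clustered without genes that differ. In CD206+ cells Lyz2 was 2.20-fold lower (2.17 to 2.23) and Lyz1 12.6-fold higher (11.4 to 13.9), being 5.42-fold higher within cluster 1 and 28.9-fold within cluster 4, the clusters that make up this class. In cluster 5 Lyz2 was 2.30-fold lower (2.25 to 2.34) and Lyz1 6.11-fold higher (5.61 to 6.66), a log2 ratio of 2.61 that was 3.42 in the larger part of the cluster described with it. In cluster 6, of 122 control and 109 Tgfbr2-KO cells, only 14 and 46 cells held UMIs of Lyz1, against 121 and 109 for Lyz2. A ratio of summed UMIs therefore need not mean a rise in every cell. Over all cells Lyz1 made up 0.952% (0.911 to 0.993) of the UMIs of both genes in the control pool. In the Tgfbr2-KO pool it made up 13.4% (13.2 to 13.5). The genes are close paralogs, and which reads of either were counted for the other was not tested here. Y-linked genes summed to 3.80 UPM in the control pool and 2.67 UPM in the Tgfbr2-KO pool.

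**Figure D1:**
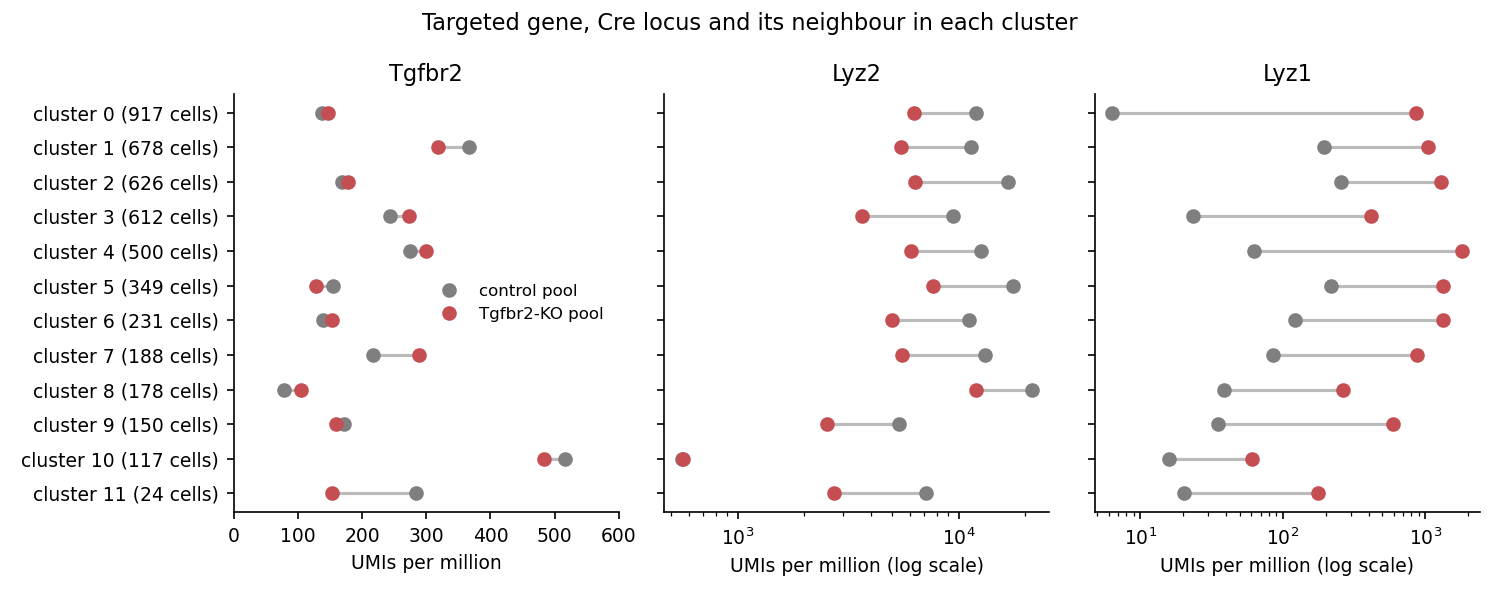
UPM of Tgfbr2 (linear axis), Lyz2 and Lyz1 (log axes) in each of the 12 clusters, with the control pool in grey and the Tgfbr2-KO pool in red. Lyz2 is lower in the Tgfbr2-KO pool in the 6 clusters with at least 100 cells in both pools, and in the small cluster 10, of cells with few UMIs, it is not.

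The kinds of donor cells found in each genotype were compared next. Most control cells were macrophages of the CD206- and CD206+ kinds, whereas about 1 in 3 Tgfbr2-KO cells lay in a cluster led by Cxcl9 and Ly6i that held few control cells. CD206- cells and the Fn1-rich cluster 5 made up smaller shares of the Tgfbr2-KO pool, and monocyte-like and proliferating cells larger ones. The shares that follow come first from clustering without the 716 genes that differed between the pools within a class, and then from clustering on all variable genes. The pools differed in depth and were sorted separately with the gate named above, and with 1 pool each the shares carry no error between mice. Shares of a pool add up to the whole, so the large share of cluster 0 among Tgfbr2-KO cells lowers the others there. On all variable genes and without cluster 0, CD206- cells were 830 of 1868 control and 596 of 1785 Tgfbr2-KO cells, still a smaller share. CD206+ cells were then 515 of 1868 and 663 of 1785, a larger share in the Tgfbr2-KO pool.

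CD206- cells, led by genes such as Cd207, Col14a1 and Ms4a7, made up 42.1% (39.9 to 44.4) of control cells and 21.5% (19.96 to 23.1) of Tgfbr2-KO cells, or 43.8% and 22.3% on all variable genes. CD206+ cells made up 29.3% (27.2 to 31.4) and 26.0% (24.3 to 27.7), or 27.2% and 24.8% on all variable genes. Without those genes, most cells of cluster 7 joined a CD206+ cluster, of which they made up 81.6%. The sign of the CD206+ difference turned at a resolution of 0.4, after thinning to 3000 UMIs and with the stricter cell filter, so its direction was not settled. Within the CD206+ class the pools sat in different clusters. Of the control cells 77.7% lay in cluster 4, led by Kazn, Cxcl13, Adgrl2, Abca1 and Spic. Of the Tgfbr2-KO cells 84.9% lay in cluster 1, led by Cd209f, Cd209g, Mmp9, Folr2 and Cd163. The CD206- class was built alike in both pools: clusters 2, 3 and 7 held 45.9%, 41.8% and 12.3% of its control cells and 41.1%, 44.5% and 14.4% of its Tgfbr2-KO cells.

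Cluster 0, led by Cxcl9, Ly6i, Ccl5, Saa3, Ly6a, Ass1 and Gbp2, held 1.37% (0.898 to 2.003) of control cells and 31.9% (30.1 to 33.7) of Tgfbr2-KO cells, or 1.48% and 33.2% on all variable genes. Its median cell had 13837 UMIs. It carried 4 classical monocyte and 4 dendritic cell markers, none of them among its leading genes, and it was given no name. It came almost wholly from 1 pool, so a state of that pool and a cell type cannot be separated in it. On all variable genes its 28 control cells also carried much Cxcl9, at 1576 UPM. Its 889 Tgfbr2-KO cells stood at 3316 UPM, 2.10-fold higher (1.93 to 2.30). Cluster 5, led by Fn1, Gpnmb, Atp6v0d2, Ctsk, Pdpn and Il6, held 13.2% (11.7 to 14.8) and 3.74% (3.05 to 4.53), or 13.1% and 3.78% on all variable genes. Monocyte-like cells, with S100a8, S100a9, Hp and Ly6c2, made up 2.004% (1.42 to 2.74) and 5.72% (4.87 to 6.67), or 2.004% and 5.24%. Proliferating cells made up 2.37% (1.74 to 3.16) and 4.56% (3.803 to 5.42), or 1.95% and 4.23%. Clusters outside these, on all variable genes, were cluster 6, led by Cd209a, Ear2, Ccl17 and Retnla and carrying 3 dendritic cell markers, with 6.43% and 4.08%, cluster 10, of cells with few UMIs, with 3.59% and 1.83%, and structural lung cells, with 0.527% and 0.524%. All clusters other than the monocyte-like and structural ones, clusters 0 and 6 with their dendritic cell markers among them, together held 97.5% and 93.8% when clustered without the genes that differed, or 97.5% and 94.2% on all variable genes. Thinned to 3000 UMIs, 94.99% (93.9 to 95.9) of control cells and 84.2% (82.7 to 85.6) of Tgfbr2-KO cells held at least 2 UMIs of the C1q genes, against 10.8% and 11.3% of monocyte-like cells.

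**Figure D2:**
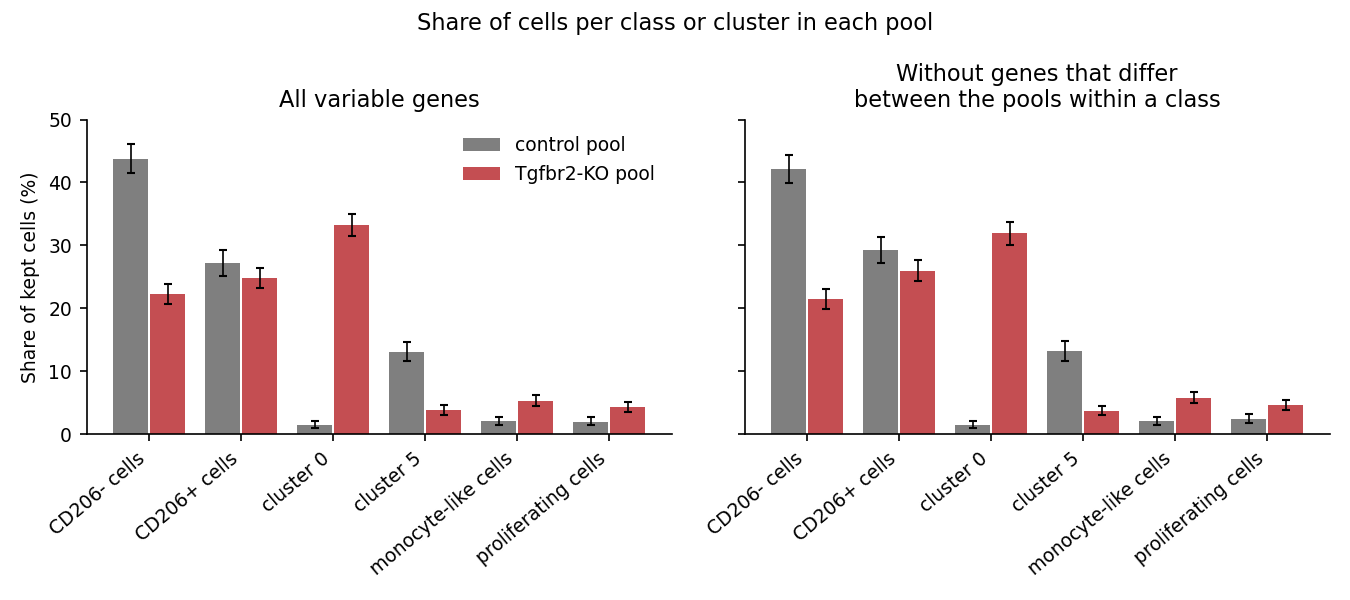
Share of kept cells (percent) in each class or cluster for the control pool (grey) and the Tgfbr2-KO pool (red), clustered on all variable genes and without genes that differ within a class; bars span the exact 95% interval. Cluster 0 holds 1.48% of control cells and 33.2% of Tgfbr2-KO cells in the first panel.

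All cells were compared to ask how the expression of the whole sorted compartment differed between the genotypes. Among the genes with the highest ratios were the chemokine genes Cxcl9 and Ccl5, the GTPase genes Iigp1 and Gbp2, which interferon induces, and Inhba. Among those with the lowest were Fn1, which marks cluster 5, the macrophage receptor Trem2, the cytokine Il1a and the TGF-beta target Pmepa1, and the lists of homeostatic macrophage and inflammatory genes were lower by their medians. Of 1736 counted genes, 198 were at least 1.5-fold higher and 161 at least 1.5-fold lower. Trimmed-mean scaling gave 156 higher and 195 lower, so which direction held more genes was not settled.

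Cxcl9, which draws T cells (ENSMUSG00000029417, chromosome 5), stood at 43.0 UPM in the control pool and 1539 UPM in the Tgfbr2-KO pool, 35.8-fold higher (33.2 to 38.6). The surface proteins Ly6i and Ly6a were 65.3-fold (50.3 to 86.3) and 63.0-fold (52.5 to 76.1) higher. Iigp1 was 29.5-fold, Gbp2 15.5-fold, Calhm6 11.7-fold and Zbp1 8.26-fold higher. Acod1, which makes itaconate, was 11.5-fold higher, and Ass1, which feeds arginine synthesis, 10.5-fold higher. Ccl5 was 7.96-fold higher. Inhba, a subunit of activin, was 36.4-fold higher (28.2 to 47.8), and 2.33-fold higher without clusters 0 and 5. Fn1, which encodes fibronectin, stood at 534 UPM and 81.9 UPM, 6.52-fold lower (6.24 to 6.82). It is a leading gene of cluster 5, and without clusters 0 and 5 it stood at 33.1 and 69.8 UPM, 2.11-fold higher. Pdpn was 3.80-fold, Ecm1 3.18-fold and the epithelial growth factor Areg 2.89-fold lower. Ecm1 and Areg, with 1.27-fold and 1.33-fold lower values, no longer met the threshold without clusters 0 and 5. Trem2, a lipid receptor of macrophages, stood at 429 and 129 UPM, 3.32-fold lower (3.19 to 3.45), and the cytokine Il1a at 497 and 163 UPM, 3.05-fold lower (2.94 to 3.16). Pmepa1, a TGF-beta target that damps the same pathway, was 3.01-fold lower (2.86 to 3.17). Cd33, Kazn, Col14a1, Rnf180 and Rgcc were 2.95-fold, 2.87-fold, 2.86-fold, 2.86-fold and 2.81-fold lower. Without cluster 0, all 12 genes with the highest and all 12 with the lowest ratios kept at least 1.5-fold in the same direction. Each fold named for them was then smaller than over all cells. Fn1 was then 4.62-fold, Pdpn 2.80-fold, Trem2 2.56-fold, Pmepa1 2.41-fold, Il1a 2.39-fold, Cd33 2.03-fold and Col14a1 1.93-fold lower. Cxcl9 was then 18.2-fold, Ly6i 8.60-fold, Ly6a 27.2-fold, Iigp1 13.5-fold, Gbp2 6.08-fold, Acod1 5.65-fold, Zbp1 4.19-fold, Calhm6 4.02-fold, Ccl5 3.01-fold and Ass1 2.36-fold higher.

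All 21 measured members of the interferon list were at least 1.5-fold higher, with a median log2 ratio of 1.61, above all 10000 random lists, and 1.36 without cluster 0. Of the TGF-beta targets 5 of 23 were lower and 3 higher, with a median of -0.33 (percentile 0.03). Skil stood at 578 and 276 UPM, while Thbs1 was higher, at 76.7 and 207 UPM. TGF-beta pathway components had a median of -0.13. Of the homeostatic genes 12 of 15 were lower (median -0.67, percentile 0), with Cx3cr1 at 301.2 and 191 UPM. Inflammatory cytokine genes were lower in 12 of 18 (median -0.72, percentile 0), Cxcl2 standing at 10492 and 5303 UPM, Tnf at 617 and 360 UPM and Nlrp3 at 791 and 400 UPM. Within CD206- and CD206+ cells the inflammatory median was smaller, at -0.31 and -0.33. The homeostatic median was -0.22 and -0.60 in these classes and -1.14 in cluster 5. How far the mix of cells shapes the values over all cells was not tested for these lists. Glycolysis genes were higher in 12 of 17 (median 0.72, or 0.22 without cluster 0). Of the classical monocyte list 9 of 18 members were higher and 3 lower, with a median of 0.64, Plac8 standing at 106 and 656 UPM and Ly6c2 at 58.8 and 273 UPM, and of the patrolling list 9 of 19 were higher and 1 lower, with a median of 0.49. The cell cycle list had a median of 0.63, and MHC class II genes 0.24.

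The remaining lists gave medians of -0.36 for the interstitial macrophage core, -0.16 for CD206+ interstitial macrophage genes, -0.27 for chemokines, -0.07 for chemokine and growth factor receptors, -0.04 for myeloid transcription factors, 0.01 for lipid and phagolysosome genes, -0.15 for extracellular matrix, 0.04 for integrins and -0.19 for alternative activation. The chemokine and alternative activation lists had means of the other sign, 0.22 and 0.21. Without cluster 0 the median was 0.43 for CD206+ interstitial macrophage genes and 0.34 for alternative activation, so neither direction was settled. Markers of other cells had medians of 2.07 for neutrophils, 0.96 for T or NK cells (2 members at the floor in 1 pool), -0.02 for B or plasma cells, -0.02 for dendritic cells, 0.52 for alveolar macrophages and 1.26 for structural cells (1 member at the floor), the epithelial gene Sftpc standing at 15.3 and 62.1 UPM. The sort left out Ly6G+ cells. In monocyte-like cells 7 of the 10 neutrophil markers were detected, with S100a8 and S100a9 among the leading genes. No neutrophil name was given to any cluster, so neutrophils among these cells are not excluded. Dissociation stress genes had a median of -0.31 and mitochondrially encoded genes -0.45. At most 2.35% of control UMIs and 7.29% of Tgfbr2-KO UMIs over all cells could be free RNA.

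**Figure D3:**
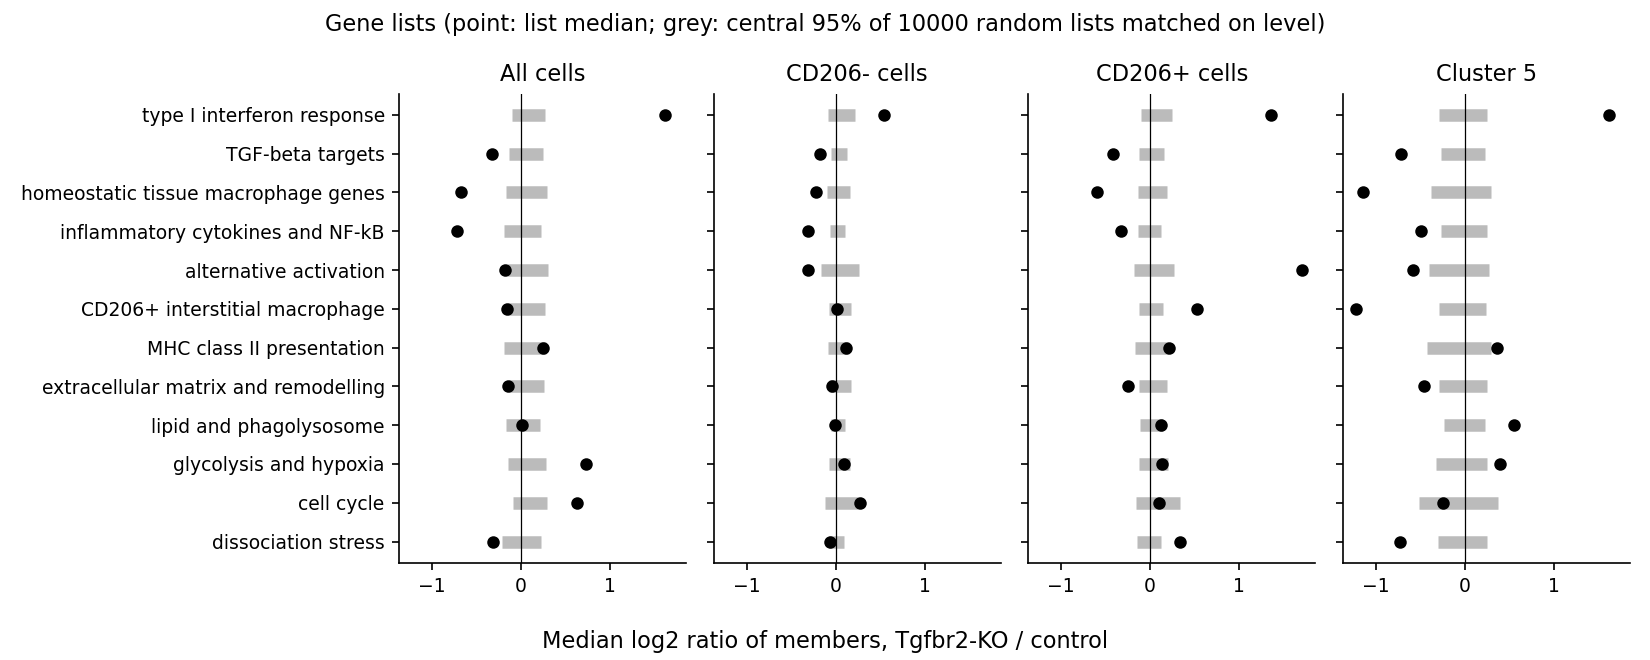
Median log2 ratio, Tgfbr2-KO over control, of 12 lists of genes in all cells and in the 3 groups named; points are list medians and grey bars the central 95% of 10000 random lists. The interferon list lies at 1.61, 0.54, 1.36 and 1.62 from the first panel to the last.

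CD206- cells were compared to ask how the pools differed within the class whose marker list holds MHC class II genes, 830 control and 596 Tgfbr2-KO cells with 5967087 and 4645857 UMIs. They differed in fewer genes than the other groups named: 42 of 1447 counted genes were at least 1.5-fold higher and 20 lower. Among the genes with the highest ratios were the chemokines Ccl8 and Cxcl9 and the interferon-inducible Ifitm3, Irf1 and Phf11b, while of the whole chemokine list 3 of 20 members were higher and 5 lower.

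The monocyte chemokine gene Ccl8 (ENSMUSG00000009185, chromosome 11) stood at 63.2 and 605 UPM, 9.58-fold higher (8.60 to 10.7), and Cxcl9 at 19.9 and 175 UPM, 8.77-fold higher (7.23 to 10.7). The log2 ratio of Ccl8, 3.26, was 2.37 without cluster 7 and 3.93 with free RNA subtracted. That of Cxcl9, 3.13, was 1.67 without the cell filter, 3.93 at an assignment probability of at least 0.99 and 3.82 with free RNA subtracted. The immunoglobulin receptor Fcgr4 was 3.07-fold higher (2.72 to 3.47), the antiviral gene Ifitm3 2.49-fold, Irf1, a transcription factor downstream of interferon, 2.44-fold and Phf11b 2.41-fold. Hdac9 was 2.42-fold, Fgl2 2.23-fold, Cd180 2.03-fold and the lipase gene Lpl 1.92-fold higher. Retnla was 5.89-fold higher on few cells, with UMIs in 39 control and 35 Tgfbr2-KO cells. In cluster 3 it was not higher, at 9.37 and 6.99 UPM on only 25 and 15 UMIs. Its log2 ratio over the class, 2.56, was -0.23 with the stricter cell filter, 0.80 in classes clustered without genes that differ and 3.46 at an assignment probability of at least 0.99, so its direction was not settled. Slc7a11, which imports cystine for glutathione, was 2.45-fold lower (2.12 to 2.84), with Srxn1 2.32-fold, Mt2 1.97-fold and Gclc 1.80-fold lower. In cluster 7 Slc7a11 stood at 52.7 and 56.1 UPM, Srxn1 at 24.96 and 24.2 UPM and Mt2 at 107 and 145 UPM, and in cluster 2 Gclc was 1.21-fold lower. The growth factor receptor brake Errfi1 was 1.89-fold lower, Il1a 1.83-fold, Clec4d 2.06-fold, Tmtc2 1.77-fold, Mpp7 1.67-fold and Ier3 1.65-fold. Cxcl13 was 1.71-fold lower over the class, while in cluster 3 it was higher, at 38.6 and 92.8 UPM, and likewise in cluster 7, at 781 and 987 UPM. Of the 12 genes with the highest and the 12 with the lowest ratios, 11 higher and 11 lower kept at least 1.5-fold in cluster 2 and as many in cluster 3. In cluster 7, of 102 and 86 cells, 12 higher and 3 lower did.

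The interferon list had 9 of 19 members higher and a median of 0.54, above all random lists. TGF-beta targets had a median of -0.18 with 1 of 21 members at least 1.5-fold lower, homeostatic genes -0.22 with 2 of 15 and inflammatory genes -0.31 with 3 of 18, each below all random lists. Patrolling monocyte genes had a median of 0.30 and MHC class II genes 0.12. Trem2 was 1.61-fold and Apoe 1.59-fold lower. Dissociation stress genes had a median of -0.07, or 0.02 without cluster 7, and mitochondrial genes -0.14. Dendritic cell genes had a median of -0.53 with 4 of 9 lower and 2 higher, and neutrophil genes 0.47 over 4 members. At most 0.852% and 1.03% of UMIs could be free RNA.

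CD206+ cells were compared to ask the same of the class with more detected CD206+ markers, 515 control and 663 Tgfbr2-KO cells with 4461126 and 6243267 UMIs. Retnla, Ccl8, Cxcl9 and the interferon list were higher over the class in the Tgfbr2-KO pool, and the TGF-beta target and homeostatic lists were lower by their medians, which in cluster 4 alone they were not. Of the chemokine list 4 of 20 members were higher and 4 lower. The values mix cluster 4, which held most control cells, with cluster 1, which held most Tgfbr2-KO cells, so genes that mark either cluster weigh in. Of 1689 counted genes, 116 were at least 1.5-fold higher and 123 lower, with 107 and 148 in cluster 1 alone and 41 and 54 in cluster 4 alone.

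Retnla (ENSMUSG00000061100, chromosome 16), a gene induced by IL-4, stood at 294 and 2933 UPM, 9.98-fold higher (9.44 to 10.6), and within cluster 1 at 1197 and 3439 UPM. Within cluster 4 it was not higher, at 30.1 and 23.8 UPM on 104 and 22 UMIs. No interval was computed there, so a fall is not shown. Ccl8 stood at 792 and 4750 UPM, 5.99-fold higher (5.79 to 6.21), and at 1665 and 5432 UPM within cluster 1 and 538 and 834 UPM within cluster 4. Cxcl9 was 15.3-fold higher (11.5 to 20.6), at 11.4 and 175 UPM, its log2 ratio of 3.93 being 1.15 in classes clustered without genes that differ, 2.61 with the stricter cell filter, 3.28 as a mean over cells and 2.73 within cluster 4. Ly6a was 72.4-fold higher (40.3 to 146), Fcgr4 7.52-fold and the complement gene C4b 5.12-fold. The lectin genes Mgl2 and Clec4b1 were 3.45-fold and 3.84-fold higher, and the protease gene Mmp12 3.59-fold. Mucl1 stood at 1.57 and 181 UPM with UMIs in 6 control and 27 Tgfbr2-KO cells, all of the latter outside cluster 4. Trem2 (ENSMUSG00000023992, chromosome 17) stood at 346 and 93.2 UPM, 3.71-fold lower (3.37 to 4.09). Pmepa1 (ENSMUSG00000038400, chromosome 2) stood at 193 and 53.5 UPM, 3.62-fold lower (3.18 to 4.12). The integrin subunit Itgav, which takes part in activating latent TGF-beta, was 3.66-fold lower, and the receptor Tgfbr1 3.12-fold lower (2.80 to 3.49). Rnf180 was 3.78-fold, Smim3 3.66-fold, Dock4 3.27-fold, Col14a1 3.26-fold, Cpd 3.25-fold, Il17ra 3.17-fold, Xylt1 3.16-fold and Kazn 2.88-fold lower. Within cluster 1 all 12 genes with the highest and all 12 with the lowest ratios kept at least 1.5-fold, though C4b was 1.86-fold and Mgl2 2.13-fold higher there, Fcgr4 12.01-fold, and Rnf180 2.35-fold, Smim3 2.11-fold, Itgav 2.29-fold, Tgfbr1 1.92-fold and Kazn 1.71-fold lower. Within cluster 4, 8 of the 12 higher and 4 of the 12 lower did, the latter being Rnf180 (1.69-fold), Smim3 (2.64-fold), Il17ra (2.08-fold) and Kazn (1.77-fold). Pmepa1 stood there at 224 and 185 UPM, Trem2 at 374 and 294 UPM and Itgav at 624 and 488 UPM, Tgfbr1 was 1.22-fold, Xylt1 1.21-fold, Cpd 1.34-fold and Dock4 1.49-fold lower, and Col14a1 was higher, at 168 and 195 UPM. Of the higher genes Ly6a was 5.39-fold, Fcgr4 2.33-fold, C4b 1.78-fold, Mmp12 1.73-fold, Mgl2 1.34-fold and Clec4b1 1.13-fold higher in cluster 4. There Ly6a rests on only 9 control and 13 Tgfbr2-KO UMIs, C4b on 44 and 21 and Fcgr4 on 80 and 50.

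TGF-beta targets were at least 1.5-fold lower in 10 of 21 and higher in 0, with a median of -0.42, below all random lists, among them Skil at 629 and 272 UPM, 2.32-fold lower. Skil was 1.86-fold lower within cluster 1 and 1.31-fold lower within cluster 4, under the threshold. The median of the list was -0.66 within cluster 1, with 11 of 21 members lower and 3 higher. It was 0.07 within cluster 4, with 2 of 21 lower and 0 higher. Homeostatic genes had a median of -0.60 with 7 of 14 lower, Cx3cr1 standing at 343 and 133 UPM. Within cluster 1 the list had a median of -0.89, and within cluster 4 it had a median of 0.00 and Cx3cr1 a log2 ratio of 0.14. The interferon list had 17 of 20 members higher and a median of 1.36. Its median was 1.24 within cluster 1, with 13 of 20 members higher and 0 lower. Within cluster 4 it was 0.54, with 8 of 17 higher and 2 lower. Alternative activation genes had a median of 1.71, which was 0.50 within cluster 1, with 6 of 12 members higher and 4 lower, and -0.27 within cluster 4, and CD206+ interstitial macrophage genes 0.53, which was -0.36 and -0.23 within them. Inflammatory genes had a median of -0.33, with -0.05 within cluster 1, where 3 of 18 were higher and 4 lower, and -0.39 within cluster 4. Patrolling monocyte genes had a median of 0.58. Markers of other cells had medians of 0.92 for dendritic cells, with 5 of 7 higher and 1 lower, 0.99 for alveolar macrophages, with 3 of 5 higher, and 0.98 for neutrophils, with 3 of 5 higher; which cells they come from was not tested. Dissociation stress genes had a median of 0.33, being 0.08 within cluster 1 and 0.10 within cluster 4, with Hspa1a at 215 and 697 UPM over the class, and mitochondrial genes -0.29. At most 0.427% and 2.90% of UMIs could be free RNA.

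Cluster 5 was compared to ask how the Fn1-rich cells differed, 248 control and 101 Tgfbr2-KO cells with 3176270 and 1880922 UMIs. At a resolution of 1.2 the cluster split into parts that the pools filled unequally. A part led by Fn1, Pdpn, Il6 and Ecm1 held 247 control and 41 Tgfbr2-KO cells, which is 13.03% (11.5 to 14.6) and 1.53% (1.10 to 2.07) of the pools. A part led by Gpnmb, Atp6v0d2, Inhba, Fabp5 and Fabp4 held 1 and 60, which is 0.0527% (0.00134 to 0.294) and 2.24% (1.72 to 2.88). The last part carried 2 alveolar macrophage markers among its leading genes. Of 1851 counted genes, 215 were at least 1.5-fold higher and 273 lower in the whole cluster, and 115 and 125 in the Fn1-led part. Values are given for the whole cluster and then, where stated, for the Fn1-led part.

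The interferon median and Inhba, a subunit gene of activin, were higher in the Tgfbr2-KO cells of both, and the TGF-beta target median, Igf1 and Apoe lower. Inhba (ENSMUSG00000041324, chromosome 13) stood at 4.72 and 1007 UPM, 213-fold higher (129 to 382), and at 4.75 and 141 UPM in the Fn1-led part. Cxcl9 was 32.4-fold higher (17.7 to 65.9), and stood at 3.48 and 71.2 UPM in the part. Rsad2 was 113-fold (47.9 to 350), Ly6a 64.2-fold, Gbp2 10.98-fold and Acod1 10.4-fold higher, and in the part 19.2-fold, 30.7-fold, 3.51-fold and 4.48-fold. In the part Rsad2 rests on only 5 control and 20 Tgfbr2-KO UMIs, Ly6a on 5 and 32 and Gbp2 on 41 and 30. The lipid genes Fabp5 and Fabp4 were 9.76-fold and 7.40-fold higher and the lysosomal Gpnmb 13.2-fold, at 98.2 and 1293 UPM. In the part Fabp4 was lower, at 27.2 and 6.06 UPM, Gpnmb stood at 97.1 and 297 UPM and Fabp5 was 2.56-fold higher. F10, Slamf8 and Thbs1 were 8.69-fold, 7.04-fold and 6.49-fold higher, and in the part 4.66-fold, 2.17-fold and 3.66-fold. Pmepa1 stood at 394 and 88.3 UPM, 4.47-fold lower (3.80 to 5.28), and at 396 and 224 UPM in the part. Fn1 was 5.05-fold lower, Igf1 4.29-fold and Apoe 3.77-fold, with 2.43-fold, 3.08-fold and 1.86-fold in the part. Rnase4, Sh3bp5, Inpp4b, Ccl12, Ramp1 and Fcrls were 5.25-fold, 4.92-fold, 4.48-fold, 4.04-fold, 3.99-fold and 3.64-fold lower, and in the part 2.29-fold, 2.19-fold, 3.16-fold, 3.61-fold, 2.05-fold and 2.17-fold. Chil3, with UMIs in 9 and 4 cells, was 5.67-fold lower, and in the part it had no UMIs in the Tgfbr2-KO pool, at least 39.2-fold lower against the floor. In the Fn1-led part 11 of the 12 genes with the highest and 12 of the 12 with the lowest ratios kept at least 1.5-fold. This count set no minimum of UMIs in the part.

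The interferon list had a median of 1.62, with 17 of 18 members higher, and 1.30 in the Fn1-led part. TGF-beta targets had a median of -0.72, with 12 of 21 lower and 2 higher, and -0.50 in the part. Homeostatic genes were lower in 13 of 13 (median -1.14, and -0.80 in the part), the interstitial macrophage core had a median of -0.85 and CD206+ interstitial macrophage genes -1.22. Lipid and phagolysosome genes had a median of 0.56 over the whole cluster. Inflammatory genes had a median of -0.49, and 0.04 in the part. Alveolar macrophage genes had a median of 0.89 over 4 members, dissociation stress genes -0.72 and mitochondrial genes -0.54. List medians without a second value hold for the whole cluster only, where the Gpnmb-led part adds 1 control and 60 Tgfbr2-KO cells. Whether they reflect the unequal filling of the parts was not tested. At most 0.358% and 1.32% of UMIs could be free RNA. In cluster 6, of 122 and 109 cells, 110 of 1559 counted genes were at least 1.5-fold higher and 70 lower, with medians of 0.62 for the interferon list, -0.22 for TGF-beta targets and -0.54 for homeostatic genes.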

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

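Of the comparisons set against each explanation here, which carry no p-value, those on the mix of cells for the interferon-inducible genes, and on shared reads and the mix of cells for the lysozyme genes, were chosen after the result was seen, as were the free RNA subtraction and the values for single clusters and for parts of cluster 5.

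Barcodes left out of the comparisons carried the interferon-inducible chemokine gene Cxcl9 above its level in control cells, 43.0 UPM. It stood at 709 UPM (612 to 817) in the 54 blank barcodes, at 144 UPM (113 to 180) in the 66 unassigned barcodes and at 968 UPM (932 to 1005) in empty droplets. Both pools were loaded together, so empty droplets hold RNA released by either pool, and Tgfbr2-KO cells carried 1539 UPM. Which pool the blank and unassigned cells came from was not tested.

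Interferon-inducible genes were higher in the Tgfbr2-KO pool. A different mix of clusters as the whole cause is argued against by the median log2 ratio of the list, which was at least 0.54 in each of the 4 classes or clusters compared. Greater depth is argued against by 906 control and 850 Tgfbr2-KO cells of 6000 to 10000 UMIs, where the median was 1.62. Cells of 1 of the 5 pooled mice, for example a mouse with an infection, cannot be told apart from an effect of the genotype, since mice carry no tag of their own: 55.6% (51.4 to 59.6) of CD206- Tgfbr2-KO cells lay above the control median of the list, against 44.7% of control cells, which may be reached by few mice or by all. The genotype therefore stays 1 of the open explanations.

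Lyz2 was lower and Lyz1 higher in the Tgfbr2-KO pool. Reads of Lyz2 counted for Lyz1 at a fixed rate would lower Lyz1 along with Lyz2, whereas the share of Lyz1 in both genes was 12.4 percentage points higher; this value comes from the same counts that raised the question, and it excludes such reads only as the cause of the higher Lyz1. Another mix of cells is argued against by the 6 clusters with at least 100 cells in both pools, where the log2 ratio of Lyz2 was at most -1.05 and that of Lyz1 at least 2.32. A chromosome segment that came with the Cre allele stays open: 0% of 4 counted genes within 5 Mb of Lyz2 differed in CD206- cells, an exact interval up to 60.2%, against 4.30% of other genes. The Cre knock-in interrupting Lyz2 is an explanation from the design for the lower Lyz2, and it was not tested itself. The cause of the higher Lyz1 stays open. Mice carry no tag of their own, so cells of some mice cannot be told apart from an effect of the genotype here either.

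TGF-beta targets were lower by their median in CD206+ cells and cluster 5 and less so in CD206- cells, a difference between groups that was not tested. Class borders drawn with genes that differ between the pools are argued against by the classes clustered without them. There the CD206+ median was -0.42 and the CD206- median -0.25. That CD206+ class again held cells of both cluster 1 and cluster 4, so the comparison does not test how these clusters were drawn. Free RNA that hides the difference in CD206- cells is argued against by the median of -0.18 after its subtraction. Within the CD206+ class depth differed little, with medians of 8293 and 8714 UMIs. The median of -0.47 in its 287 and 299 cells of 6000 to 10000 UMIs could therefore say little about depth. In cluster 5, where the median cell had 11436.5 and 17584 UMIs, depth was not tested. Within cluster 4, however, the median was 0.07, so the pattern in CD206+ cells rests on cluster 1 and on the unequal filling of both clusters. Whether the 100 Tgfbr2-KO cells of cluster 4 may have kept the receptor, or were placed there because their targets resemble control cells, stays open, as 3′ counts do not show the deletion.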

How the results depend on the processing

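Thinning before clustering, clustering without the wider set of genes, re-clustered classes, single clusters or their parts, all cells without some clusters, and the subtraction of free RNA were chosen after the data had been seen. Of 64 alternative values for shares 55 stayed within the interval of the value reported and 9 moved. For numbers of genes 34 of 45 stayed within 1.5 times, for list medians 322 of 410 stayed, and for single genes 250 of 370. The sign turned in 18 list medians and 6 single genes, and in 1 and 4 of these the value reported was at least 1.5-fold, which is called reversed here. No paired analysis was possible, because there is 1 pool per genotype. Leaving out Scrublet doublets gave no separate values, since it marked 1 of 4570 cells.

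The difference in the CD206+ share, -2.37 percentage points, was 4.05 at resolution 0.4, 0.0341 under the stricter cell filter, -9.21 with 1000 variable genes and 6.70 after thinning to 3000 UMIs. The CD206- difference of -21.5 kept its sign, at -26.5 under the stricter cell filter, -31.4 at resolution 0.4 and -32.5 after thinning. The cluster 0 difference of 31.8 was 33.8 at resolution 0.4 and 26.3 when clustered without genes that differed within a class or over all cells. The difference for all clusters other than monocyte-like and structural ones was -3.23. The share of cells with at least 2 C1q UMIs after thinning, another measure that uses no clusters, differed by -10.8. In the alternative clusterings cells pass between classes whose names rest on conditions set after the clusters were seen. The cause of each shift was not tested. The cluster 5 difference stayed between -9.45 and -8.22, the monocyte-like between 2.31 and 3.72, and the proliferating between 1.85 and 2.42.

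The numbers of genes at least 1.5-fold different were 359 in all cells, 62 in CD206- cells, 239 in CD206+ cells and 488 in cluster 5. A minimum of 20 UPM gave 934, 216, 675 and 1247, as more genes entered, and a fold of 2 gave 132, 15, 87 and 207. All cells without cluster 0 gave 180 and the larger part of cluster 5 gave 240. Of the CD206+ clusters, cluster 4 alone gave 95 and cluster 1 alone 255; the cause was not tested. Trimmed-mean scaling turned the split in all cells to 44.4% higher, from 55.2%, and moved the median of all genes by -0.08, the largest shift of any scaling.

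Retnla reversed most often, with log2 ratios of -0.23 in CD206- cells under the stricter filter, -0.34 in cluster 4 alone and -2.86 in the larger part of cluster 5. Reversed means the sign only: the value in cluster 4 rests on 104 and 22 UMIs, and no interval was computed for it. In cluster 4 alone Cx3cr1 was at 0.14 and alternative activation at -0.27. The cause was not tested. Over the alternatives the interferon median stayed between 1.36 and 1.79 in all cells, 0.45 and 0.69 in CD206- cells, 0.54 and 1.42 in CD206+ cells and 1.30 and 1.70 in cluster 5. TGF-beta targets stayed between -0.26 and -0.17 in CD206- cells and -0.80 and -0.50 in cluster 5, and ran from -0.66 to 0.07 in CD206+ cells. Cxcl9 ran from 1.67 to 3.93 in CD206- cells and from 1.15 to 4.36 in CD206+ cells. Depth limits genes at or under the floor. Differences between mice could not be measured with 1 pool per genotype.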

Other observations

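The families of interferon-inducible GTPases were listed after the values had been seen. Of the 16 genes listed, 15 were measured over all cells and 15 were at least 1.5-fold higher in the Tgfbr2-KO pool, with a median log2 ratio of 3.18. In CD206- cells 12 of 13 were higher (median 1.34), in CD206+ cells 13 of 13 (median 2.04) and in cluster 5 11 of 11 (median 2.83). These families answer to interferon gamma as well as to type I interferon. Transcripts of interferon gamma itself were under the floor of 3 UMIs, with 1 UMI of Ifng in the control pool and 2 UMIs in the Tgfbr2-KO pool, so a source of it among the sorted cells was not detectable at this depth. Ifnb1 stood at 6.07 UPM in the control pool and 1.85 UPM in the Tgfbr2-KO pool.

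Nos2, which makes nitric oxide, had 9 UMIs in the control pool and 1235 UMIs in the Tgfbr2-KO pool, where 126 cells (4.71%) held them. Tgfb1 stood at 260.02 UPM and 222 UPM, Il12b at 10.6 and 22.7 UPM and Ciita at 55.5 and 85.9 UPM. These genes were also chosen after their values had been seen.

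At a resolution of 1.2 cluster 0 split into a part led by Ccr7, Dnase1l3 and Il12b, which held 1.05% of control and 20.4% of Tgfbr2-KO cells, and a part led by Saa3, Ly6i and Nos2, which held 0.369% and 12.7%. Over the whole Tgfbr2-KO pool 111 cells held UMIs of Ccr7 and 61 cells UMIs of Il12b, so most of the 545 Tgfbr2-KO cells of the first part held neither. The first part carried 2 dendritic cell markers among its leading genes, and 5 dendritic cell markers were detected in it.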
